A study of Mus musculus with 6 samples.

How the data were processed

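Chromatin bound by γH2AX, the phosphorylated form of the histone variant H2AX that spreads around DNA double-strand breaks, was sequenced from mIMCD3 cells, a line from the inner medullary collecting duct of the mouse kidney. The 6 libraries fell into 5 groups. Control, bleomycin, UV and high NaCl had 1 library each, and the return group had 2. Return cells had been moved from high NaCl medium back to control medium shortly before fixation. Nothing in the labels says that the 2 return libraries came from separate cultures, so p-values measure only the spread between these libraries, which can be technical. An input library was not used here, so every value is relative to another γH2AX library and none is an enrichment over genomic DNA.

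Per the labels' protocols, formaldehyde-fixed chromatin was cut with micrococcal nuclease (MNase) to mostly single nucleosomes, precipitated with an antibody to γH2AX, amplified and size selected on a gel. Reads from a Solexa 1G Genome Analyzer were then mapped with the Solexa Analysis Pipeline, and only reads with a unique match were kept. The aligner's version and the genome build are not given in the sources used here. The labels mention a summary in 300 bp windows, while the files used here list single reads. Each deposited file has 6 columns and no header, with 1 line per read of 25 bp giving chromosome, start, end, a match descriptor, a score and a strand. The score in the deposited files is the aligner's own value per read, a whole number from 4 to 53 whose scale is not given in the sources used here, and it was used only to describe libraries and in an alternative restricted to reads at 53.

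The build was inferred from where reads end. No read passed the end of any of 20 chromosomes in mm8, and the largest distance from the last read to a chromosome end was 50019 bp. Reads passed the end of 5 chromosomes in mm9 and of 8 in GRCm38. All positions below are therefore given as they stand in the files, 1-based, on a build whose chromosome lengths fit mm8. The gene table used here is on GRCm38, and positions were not converted. It served only to count protein-coding genes per chromosome. Gene deserts, gene bodies, annotation classes, profiles around transcription start sites, gene density or GC content in windows and 12 gene lists were therefore not analysed here, and no window is given a gene name.

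Reads were counted by their 5′ end in windows of 10 kb, 100 kb and 1 Mb on 19 autosomes and the X chromosome. Counts were scaled to CPM by each library's total on these chromosomes and taken as log2(CPM + 0.5), so a log2 ratio understates the change where a window holds few reads. Signal below means a share of a library's reads. A rise or fall of γH2AX over the whole genome cannot be seen in such shares, so a lower share need not mean less of the mark. Because the files carry no column of counts, the count model planned for count tables was replaced by its planned substitute, limma 3.58.1 with an intensity trend in R 4.3.3. All 6 libraries entered a single fit with 5 groups. The spread came from the 2 return libraries alone (1 residual degree of freedom, shared over windows), and each lone library was assumed to vary like them. Windows of 100 kb with a mean of at least 20 reads entered (25269 of 26290), p-values were two-sided, and windows with a Benjamini-Hochberg adjusted p under 0.05 were counted. Ratios of a lone library to control have no replicate check. Their 95% intervals come from the exact Clopper-Pearson interval of the reads and cover counting error only, since reads amplified by PCR are not independent molecules.

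The fit was tested on simulated data with 25269 windows, of which 50 were changed at each of several sizes. Every library was given the spread of the return pair. Recovery after adjustment depends on how many windows change, so these rates hold for few changed windows and not for a genome-wide shift. For high NaCl against control it called 80% of windows raised by 1 on the log2 scale and 60% of those lowered by 1. At a change of 0.5 it called 10% and 4%. For return against control the shares were 94% and 80%, then 16% and 8%. Among 25069 unchanged windows, 3 and 4 were called.

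For each comparison the text names windows by a rule set for the case that genes cannot be placed: the 5 highest and the 5 lowest 1 Mb windows among those with a mean of at least 100 reads, with values from the same fit on 1 Mb windows. The last window of a chromosome covers only part of 1 Mb. Reads ended at 155.03 Mb on chromosome 4, 145.13 Mb on chromosome 7, 98.25 Mb on chromosome 16 and 159.87 Mb on chromosome 3. Relations across chromosomes used Spearman's rho and Pearson's r with two-sided permutation p-values from 100000 resamples, adjusted over 6 relations. Libraries were thinned to equal depth for the share of reads in the top 1% of 10 kb windows. The designs, comparisons, naming rule and most alternatives were fixed before the data were examined. Those alternatives were TMM and median-of-ratios scaling, filters on low windows, a pseudocount of 2, at most 1 read per position and strand, and other window sizes. Runs of windows, density classes, fragment lengths, chromosome ends, alternatives on aligner score, on the top 0.1% of 10 kb windows and on the X chromosome were added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

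Depth ranged from 8464933 reads in return replicate 1 to 19369842 in bleomycin. Aligner scores split the libraries in a way their groups do not explain. Reads at score 9 made up 0.185% of the high NaCl library and 0.244% of return replicate 1, against 1.48% to 1.66% in the other libraries. Among reads with a mismatch, the share with the letter A was graded: 47.7% in high NaCl and 55.4% in return replicate 1, 40.5% in return replicate 2, and 26.6% to 33.2% in bleomycin, control and UV. High NaCl and return replicate 1 are called the first score pattern below, and control, bleomycin, UV and return replicate 2 the second. High NaCl and control differ in pattern, so no value within a pattern can be given for that comparison. Return replicate 2 against control and return replicate 1 against high NaCl are comparisons within a pattern.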

Results

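The positions of γH2AX were mapped in mouse mIMCD3 kidney cells to ask where DNA breaks lie in cells kept in high NaCl, in relation to gene-poor parts of the genome. Control medium had 300 to 320 mosmol/kg. High NaCl cells spent 22 h at 500 mosmol/kg, and return cells spent the same time there followed by 15 min in control medium. UV cells received 15 J/m2 of ultraviolet light, and bleomycin cells were given 5 µg/ml of this DNA-cutting drug for 30 min. On the autosomes and X, the files held 12698873 reads for control, 19362397 for bleomycin, 12369507 for UV, 10020978 for high NaCl, and 8459216 and 8946407 for return replicates 1 and 2. Reads beyond the first at each position and strand made up 33.6% of the bleomycin library and 2.27% to 6.22% of the other libraries. Gene deserts themselves were not analysed here, and gene content is given per chromosome only.

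The return libraries stood apart from the rest in how signal was spread over the genome. Across 25269 windows of 100 kb, the return replicates resembled each other (Spearman rho 0.91) and differed most from control (0.39 and 0.25). Bleomycin was closest to control (0.93), followed by high NaCl (0.88) and UV (0.83), and high NaCl and UV resembled each other (0.93). These coefficients describe windows within libraries, and windows are not independent replicates. At equal depth, the top 1% of 10 kb windows held 4.88% and 5.88% of reads in the return replicates, 4.33% in control, 4.11% in high NaCl, 4.07% in bleomycin and 3.96% in UV. Without the top 0.1% of 10 kb windows the shares were 2.87% and 3.23% in return and 2.68% in control.

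In cells returned to control medium, the share of reads differed from control over large blocks of the genome. Chromosome 6 from 132000001 to 133000000 rose 2.45-fold over control (log2 1.29 ± 0.03, SD, n = 2, adjusted p = 5.4e-07). Similar rises occurred on chromosome 13 from 87000001 to 88000000 (2.36-fold, log2 1.24 ± 0.04), chromosome 8 from 52000001 to 53000000 (2.29-fold, 1.20 ± 0.04) and chromosome 10 from 103000001 to 104000000 (2.29-fold, 1.20 ± 0.02), each with the same adjusted p. Signal fell to 0.499 of control on chromosome 5 from 36000001 to 37000000 (SD 0.15 on the log2 scale, adjusted p = 1.1e-06) and on chromosome 8 from 125000001 to 126000000 (-0.98 ± 0.11, adjusted p = 1.3e-06). The fall on chromosome 5 from 31000001 to 32000000 (-0.99 ± 0.52, adjusted p = 0.0035) was larger in return replicate 2 (-1.36) than in replicate 1 (-0.62).

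The rule also named 3 other windows, of which 1 passed the test. Chromosome 17 from 39000001 to 40000000 had the highest mean (log2 1.31 ± 2.30), but its values were -0.31 in replicate 1 and 2.93 in replicate 2, and its adjusted p was 0.053. The window next to the chromosome 5 fall, from 32000001 to 33000000, had -1.03 ± 0.54 and an adjusted p of 0.19. The lowest mean, -1.20 ± 0.25, belonged to the last window of chromosome 4, from 155000001 to 156000000, with 174 reads in control and 42 and 58 in return (adjusted p = 0.027). Reads on that chromosome ended at 155.03 Mb, so this window covers only a small part of 1 Mb.

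Changed windows in return lay side by side. Of 25269 windows of 100 kb, limma with Benjamini-Hochberg adjustment called 6844 higher and 8254 lower than in control, whose single library is assumed to vary like the return replicates. Runs of 1 Mb or more held 78.9% of the higher windows and 46.0% of the lower windows, against 0.0855% and 0.174% when calls were shuffled along chromosomes. The longest raised run spanned 10.7 Mb on chromosome 1, from 109300001 to 120000000. The longest lowered run spanned 9.2 Mb on chromosome 8, from 122200001 to 131400000. Scaling decided which direction prevailed: higher windows were 45.3% of calls as scaled by total reads, 56.6% with TMM factors (7614 higher, 5840 lower) and 58.3% with median-of-ratios factors. The median log2 ratio of all windows was -0.15 as scaled by total reads and -0.04 with TMM, so the named changes of about 1 on the log2 scale keep their sign under both.

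Regions sparsely covered in control and bleomycin held a larger share of reads in return, and densely covered regions held a smaller share. Autosomal 1 Mb windows were ranked by their density in the bleomycin library, which plays no part in the ratio of return to control. Over all 1 Mb windows, bleomycin followed control closely (rho 0.97), while return followed it weakly (0.41 and 0.31). Any library with a profile unlike that of control would tend to rise in sparse classes and fall in dense ones. The direction is therefore not a result separate from that low likeness. In the sparsest 482 windows the median log2 ratio to control was 0.51 ± 0.04 in return (SD, n = 2), and in the densest 482 it was -0.49 ± 0.04. High NaCl gave 0.21 and -0.15 in the same classes, and UV gave 0.24 and -0.16. The spread of 1 Mb ratios to control from the 5th to the 95th percentile was 1.63 in return replicate 1 and 1.91 in return replicate 2, on the log2 scale. Return replicate 2 shares the second score pattern with control, so the latter value is a comparison within that pattern. Between the return replicates the spread was 0.50.

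**Figure D1:**
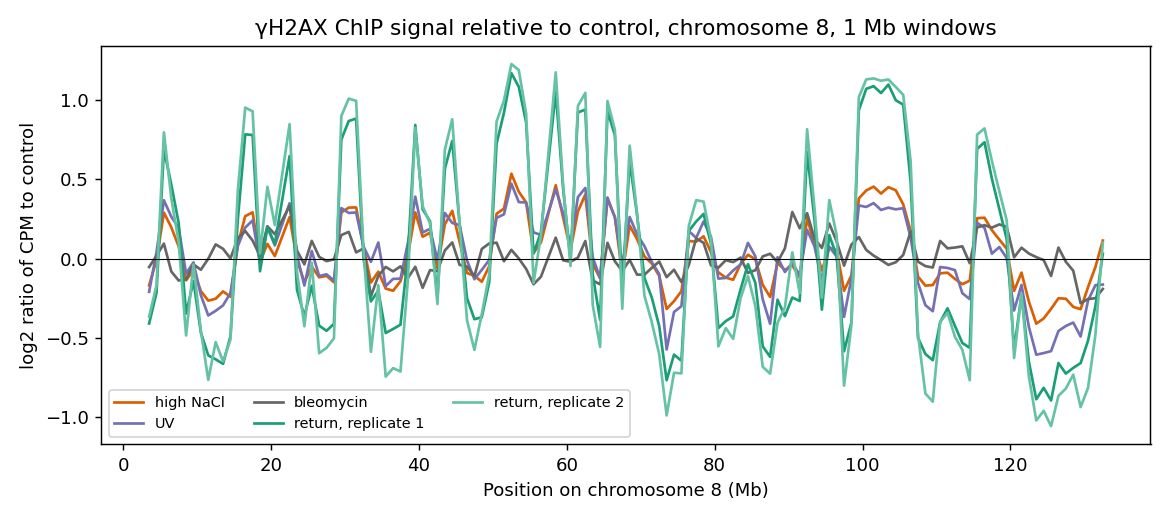
Signal along chromosome 8 relative to control, as log2 ratios of CPM (vertical axis) in 1 Mb windows by position in Mb (horizontal axis), with 1 line per library. Both return replicates peak in the window from 52000001 to 53000000 (1.17 and 1.23) and are low from 125000001 to 126000000 (-0.89 and -1.06), while high NaCl and UV trace similar but shallower peaks and troughs.

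For cells still in high NaCl, the comparison with control addressed where γH2AX lay during the stress. The regions with the highest ratios included several that rose in return. Chromosome 8 from 52000001 to 53000000 had a log2 ratio of 0.53 (1.45-fold, 95% counting interval 0.47 to 0.60) and chromosome 6 from 132000001 to 133000000 had 0.52 (0.43 to 0.61). The other high windows were on X from 116000001 to 117000000 (0.53), chromosome 17 from 18000001 to 19000000 (0.52) and chromosome 2 from 81000001 to 82000000 (0.51). Chromosome 17 from 39000001 to 40000000 had the lowest ratio (-0.83), followed by the last window of chromosome 4 (-0.65, on 86 reads). In the former, 7487 of 9346 control reads lay between 39450001 and 39460000, where control had 2.14 times the median CPM of the other libraries without return replicate 2. Adjacent windows on chromosome 8 from 123000001 to 125000000 had -0.41 and -0.38, and chromosome 11 from 118000001 to 119000000 had -0.36.

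None of the high NaCl differences passed the test. limma with Benjamini-Hochberg adjustment called 0 of 25269 windows of 100 kb, and TMM and median-of-ratios scaling also gave 0. An unadjusted p under 0.05 occurred in 1414 windows, close to the share that threshold passes when nothing changes. The test's spread comes from the return replicates, which differ in score pattern and short fragments. Their 100 kb log2 differences had an SD of 0.233, against 0.238 between control and high NaCl and 0.155 between UV and high NaCl. That spread may be too wide for the lone libraries, so 0 calls do not show that nothing changed. In data simulated for this comparison at 100 kb, 10% of windows raised by 0.5 on the log2 scale were called and 80% of those raised by 1. Few windows were changed in that simulation, so these rates do not measure recovery of a genome-wide shift. The 10 named 1 Mb windows had adjusted p-values of 0.287 to 0.684. High NaCl and control also differ in score pattern, so the pattern and the treatment cannot be told apart within this comparison.

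The high NaCl profile followed the return profile at a smaller scale. Across 1 Mb windows, log2 ratios to control in high NaCl and return had a Pearson r of 0.96 and a covariance of 0.111. Unchanged libraries simulated against the same control gave 0.58 and 0.0132, and the difference in covariance was 0.0974. Each simulated library had the spread of the return pair, which may be too wide for high NaCl and control, so the simulated covariance may be too large. Return was unchanged in that simulation too, so its r is no reference for real return, and only the covariances are compared. With separate reference libraries on the autosomes, high NaCl minus bleomycin rose with return minus control with a slope of 0.27 (95% interval from resampling chromosomes 0.26 to 0.29). Windows are not independent replicates, and those values describe these libraries.

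Among the 5 highest windows named by the rule, return exceeded high NaCl most clearly on chromosome 13 from 87000001 to 88000000 (log2 0.80 ± 0.04, n = 2, adjusted p = 0.00093). X from 106000001 to 107000000 was similar (0.80 ± 0.13, adjusted p = 0.00093). Signal was lower in return on chromosome 5 from 36000001 to 37000000 (-0.67 ± 0.15, adjusted p = 0.00093), chromosome 4 from 132000001 to 133000000 (-0.68 ± 0.24, adjusted p = 0.0016), the last window of chromosome 7 (-0.76 ± 0.02, adjusted p = 0.012) and chromosome 5 from 31000001 to 32000000 (-0.75 ± 0.52, adjusted p = 0.031). Chromosome 5 from 32000001 to 33000000 had -0.81 ± 0.54 and did not pass (adjusted p = 0.32). Chromosome 17 from 39000001 to 40000000 passed (2.14 ± 2.30, adjusted p = 0.0065) on the strength of replicate 2 (3.76, against 0.51 in replicate 1). X from 3000001 to 4000000 and chromosome 7 from 22000001 to 23000000 had 0.98 ± 1.19 and 0.82 ± 0.22 and did not pass (adjusted p = 0.059 and 0.11).

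This comparison asks what 15 min in control medium changed, and limma called 4367 windows of 100 kb higher and 4174 lower. With TMM factors the counts were 5619 and 1545, and with median-of-ratios factors 5441 and 1567, so higher windows were 51.1% of calls as scaled by total reads and 78.4% and 77.6% otherwise. Over 1 Mb windows the balance turned, with 573 higher and 733 lower. The longest raised run spanned 7.2 Mb on chromosome 8, from 99100001 to 106300000. Lowered windows were more scattered, and their longest run spanned 1.8 Mb on chromosome 11, from 96100001 to 97900000. Runs of 1 Mb or more held 56.1% of the higher windows and 5.25% of the lower windows. Within the first score pattern, return replicate 1 against high NaCl had a 5th to 95th percentile spread of 1.03 on the log2 scale over 1 Mb windows.

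UV light, a source of damage other than salt, gave its highest ratios on the X chromosome. All 5 of the highest 1 Mb windows lay there, with log2 ratios of 0.54 to 0.59, led by the window from 118000001 to 119000000 (0.59, 95% counting interval 0.48 to 0.70). In control, X held 0.296 times the reads per Mb of the autosomes, and the sparsest autosomal windows also rose in UV (median 0.24). The lowest windows were the last of chromosome 4 (-0.88, on 89 reads), the last of chromosome 7 (-0.71), chromosome 10 from 79000001 to 80000000 (-0.67) and from 80000001 to 81000000 (-0.66), and chromosome 5 from 36000001 to 37000000 (-0.66). These 10 windows did not pass the test (adjusted p = 0.224 to 0.386).

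At 100 kb, limma called 8 windows lower and 0 higher in UV than in control, with 2340 at an unadjusted p under 0.05. The 8 windows fell by 0.99 to 1.14 on the log2 scale (adjusted p = 0.0094 to 0.029) and lay on chromosome 2 (from 30500001, 167400001 and 167600001), chromosome 8 (from 125100001 and 129700001), chromosome 10 (from 80300001) and chromosome 11 (from 96100001 and 119700001). All 8 were also lower in return, where 2.61 would be shared by independent lists, though part of that excess can come from the shared control library. The count was 48 with TMM factors, 8 with median-of-ratios factors, 2 with reads at the top aligner score and 0 over 1 Mb windows. Log2 ratios of UV and return to control had an r of 0.90 and a covariance of 0.117 over 1 Mb windows. Simulated libraries with both UV and return unchanged gave 0.58 and 0.0133. Only the covariances are comparable, and their difference was 0.103. Each simulated library had the spread of the return pair, which may be too wide for UV and control, so the simulated covariance may be too large.

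The bleomycin library was the one most like control, a ranking that rests on 1 library per group and was not tested. The highest 1 Mb windows were 4 on chromosome 12, starting at 24000001, 20000001, 18000001 and 19000001, and 1 on chromosome 14 from 41000001 to 42000000, with log2 ratios of 0.48 to 0.53. The lowest was chromosome 17 from 39000001 to 40000000 (-1.32), the window in which control is itself raised, followed by chromosome 2 from 98000001 to 99000000 (-0.50), X from 138000001 to 139000000 (-0.44), chromosome 16 from 98000001 to 99000000 (-0.41) and chromosome 3 from 159000001 to 160000000 (-0.39). None passed the test (adjusted p = 1.00). limma called 0 windows of 100 kb, and TMM and median-of-ratios scaling also gave 0. An unadjusted p under 0.05 occurred in 451 windows, below the share that threshold passes when nothing changes. The SD of 100 kb log2 differences was 0.233 between the return replicates and 0.188 between control and bleomycin. The spread assumed for the lone libraries may thus be too wide, and 0 calls do not show that nothing changed. Over 1 Mb windows the r between bleomycin and return ratios to control was 0.28 and the covariance 0.0193. Unchanged simulated libraries gave 0.58 and 0.0133, and the difference in covariance was 0.00605. Each simulated library was given the spread of the return pair. The SD of 1 Mb log2 differences was 0.173 between the return replicates and 0.120 between control and bleomycin. The simulated covariance may thus be too large, and the difference in covariance too small. Return was unchanged in the simulation, while real return varied widely, which lowers r for any partner. The r of 0.28 therefore does not show that bleomycin resembled return less than unchanged libraries would.

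Return also differed from both agents that damage DNA directly. Against bleomycin, windows on X rose from 59000001 to 60000000 (log2 1.30 ± 0.18, n = 2, adjusted p = 1.2e-06) and from 80000001 to 81000000 (1.29 ± 0.11, adjusted p = 8.1e-07), and limma called 6188 windows of 100 kb higher and 7368 lower. Signal fell on chromosome 8 from 123000001 to 124000000 (-0.96 ± 0.09), chromosome 5 from 114000001 to 115000000 (-0.93 ± 0.03), chromosome 17 from 27000001 to 28000000 (-0.93 ± 0.01) and chromosome 4 from 140000001 to 141000000 (-0.91 ± 0.16). With TMM factors the split was 7148 higher and 4806 lower. Against UV, chromosome 10 rose from 103000001 to 104000000 (0.83 ± 0.02) and from 124000001 to 125000000 (0.83 ± 0.01), as did chromosome 2 from 86000001 to 87000000 (0.82 ± 0.05), each with an adjusted p of 0.00026. The falls against UV were shallower, at -0.53 to -0.50 on chromosomes 5, 7, 11 and 18. limma called 4081 windows of 100 kb higher and 1983 lower than in UV, and with TMM factors 5694 and 63. Over 1 Mb windows the balance turned, with 559 higher and 848 lower. In both comparisons chromosome 17 from 39000001 to 40000000 had the highest mean, again through replicate 2 (4.25 against 1.00 for bleomycin, 3.45 against 0.21 for UV), and X from 3000001 to 4000000 ranked next in both (1.31 ± 1.19 and 0.88 ± 1.19), likewise through replicate 2 (2.15 against 0.47 for bleomycin, 1.72 against 0.03 for UV). The latter window passed against bleomycin (adjusted p = 0.011) and not against UV (0.084). Chromosome 2 from 98000001 to 99000000 and the last window of chromosome 4 were among the extremes against bleomycin (1.28 and -0.90) and did not pass (adjusted p = 0.28 and 0.094).

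Whole chromosomes shifted as well. The X chromosome took 1.26 and 1.41 times its control share of reads in return replicates 1 and 2 (1.34 ± 0.11), 1.20 times in UV, 1.11 times in high NaCl and 0.975 times in bleomycin. Chromosome 19 took 0.857 ± 0.007 and chromosome 11 took 0.884 ± 0.004 of their control share in return, and 0.960 each in high NaCl. Chromosome 17 took 0.986 of its control share in return replicate 1 and 1.15 in replicate 2. The value in replicate 2 rested largely on 1 window of 10 kb, from 39450001 to 39460000. That window held 47741 of the 390558 chromosome 17 reads in replicate 2, against 7487 of 482595 in control. These ratios were not tested chromosome by chromosome. X was sparsely covered in control, at 0.296 times the autosomal reads per Mb, and sparse autosomal windows rose as well. Whether the rise of X is separate from theirs was not tested.

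Chromosomes with fewer protein-coding genes per Mb took a larger share in high NaCl (Spearman rho -0.63 over 20 chromosomes, permutation p = 0.0038, adjusted 0.0076) and UV (-0.65, p = 0.0030, adjusted 0.0076). Pearson's r was -0.58 (p = 0.0088) and -0.49 (p = 0.031), and without chromosomes 7 and 11, the farthest from the median gene density, it was -0.60 and -0.51. For return, rho was -0.47 (p = 0.037), which did not pass adjustment (0.055), with -0.64 in replicate 1 (adjusted 0.0076) and -0.42 in replicate 2 (adjusted 0.085). With at most 1 read per position and strand the rho for return was -0.53 (p = 0.018), and without the top 0.1% of 10 kb windows -0.51 (p = 0.023), both before adjustment. Pearson's r for return was -0.49 (p = 0.029, adjusted 0.037) and -0.47 without chromosomes 7 and 11. Bleomycin went the other way, with a rho of 0.38 (p = 0.094, adjusted 0.094) and an r of 0.60 (p = 0.0052, adjusted 0.016) that rested on chromosomes 7 and 11, since it was 0.30 without them. With at most 1 read per position and strand the rho for bleomycin was 0.61 (permutation p = 0.0052), and without the top 0.1% of 10 kb windows it was 0.46 (p = 0.042), both before adjustment. Of these libraries UV, bleomycin and return replicate 2 share the second score pattern with control, while high NaCl and return replicate 1 do not. Chromosomes are not replicates: each ratio sets a library against the same control library, so these p-values describe the libraries and not the treatments.

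**Figure D2:**
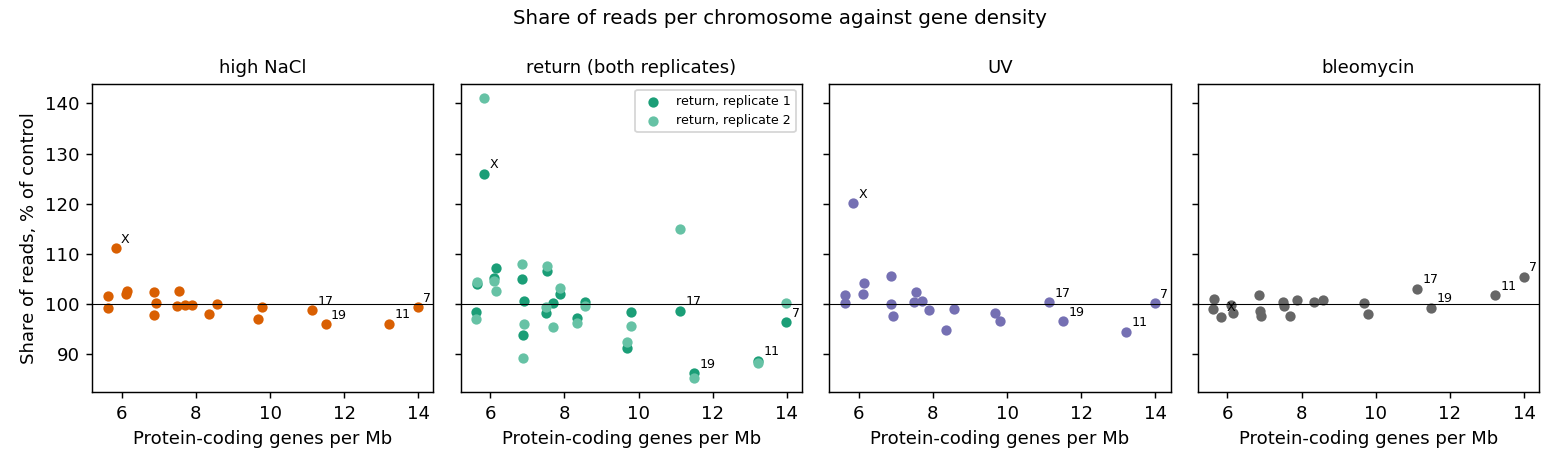
Share of reads on each of 20 chromosomes as a percentage of the control share (vertical axis) against protein-coding genes per Mb (horizontal axis), with 1 point per chromosome and library and the X and chromosomes 7, 11, 17 and 19 labelled. The X chromosome stands highest in high NaCl (111%), return (126% and 141%) and UV (120%), and chromosomes 11 and 19 lie below 100% in these libraries.

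Fragment lengths differed between libraries and moved with the groups that shifted most. Among distances above 40 and up to 300 bp between 5′ ends on opposite strands, the profile peaked at 149 bp in control, at 1.78 times the level at longer distances, and at 150 bp in high NaCl, both close to the length of DNA in a nucleosome. It peaked at 104 bp in UV (1.28 times) and 56 bp in return replicate 2 (1.31 times). Bleomycin and return replicate 1 had low peaks at 149 and 148 bp (1.14 and 1.20 times), and distances near the read length, below that range, were above the peak in bleomycin and both return replicates. Short fragments of 40 to 120 bp made up 19.98% of the excess over the level at longer distances in control (SD over 19 autosomes 1.57), 19.2% in bleomycin, 16.9% in high NaCl (SD 3.88), 65.2% in UV, and 44.8% and 70.3% in return.

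**Figure D3:**
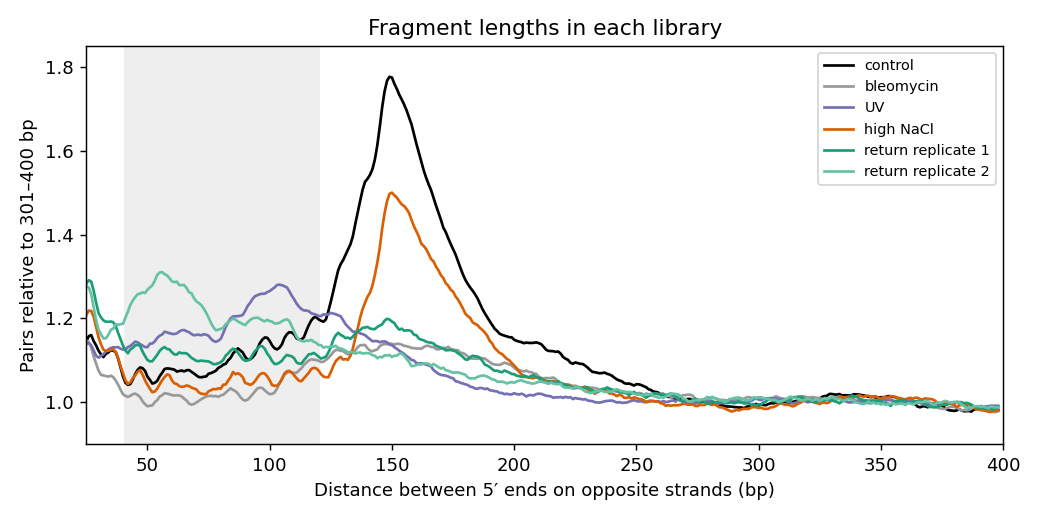
Number of pairs of 5′ ends on opposite strands at each distance in bp (horizontal axis), relative to the level from 300 to 400 bp (vertical axis), with 1 line per library smoothed over 5 bp. The shaded band marks short fragments. Above 40 bp, control and high NaCl peak at 149 and 150 bp, UV at 104 bp and return replicate 2 at 56 bp.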

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

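All tests in this part were chosen after the results they bear on had been seen. Chromosome Y lay outside every comparison and drew attention because its share of reads exceeded that of control in several libraries. Its CPM over all reads in a file was 404 in control (95% counting interval 393 to 415), 384 in bleomycin, 430 in UV, 497 in high NaCl, and 675 and 651 in return replicates 1 and 2. No biological or technical explanation was tested for it.

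The first pattern is the shift of signal between 1 Mb windows in return. A sequencing run as marked by aligner scores is argued against because return replicate 2 and control share a score pattern and still differed with a 5th to 95th percentile spread of 1.91, against 0.50 between the return replicates, though by the share of A among mismatches return replicate 2 (40.5%) lay between control (31.7%) and high NaCl (47.7%). Loss of cells in S phase, when early-replicating regions have up to 2-fold more copies, could change copy number by at most 1 on the log2 scale. The smaller spread was 1.63, so loss of these copies is argued against as the whole cause. The bound covers DNA copies only, and a change of the γH2AX mark itself with the cell cycle was not tested and stays open. More extensive MNase digestion stays open: short fragments were 20.4 percentage points more common in UV (spread 0.72) than in return replicate 1, but return replicate 2 had both the most short fragments (70.3%, against 65.2% in UV) and the widest spread. Run differences that scores do not mark, a part played by copy number, GC bias in amplification (not analysed here) and the return to control medium itself also remain open.

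The second pattern is the smaller shift in high NaCl, with a spread of 0.63. Score patterns and the treatment cannot be told apart: return replicate 1 minus return replicate 2, which differ in pattern as high NaCl and control do, had a slope of -0.11 on UV minus bleomycin, but these replicates also differ in shift (1.63 and 1.91) and in short fragments (44.8% and 70.3%), so the slope does not isolate the pattern. More extensive digestion was not detected, since short fragments in high NaCl minus control came to -3.11 percentage points. The SDs over autosomes, 3.88 in high NaCl and 1.57 in control, measure spread between chromosomes and not between libraries. With 1 library each, a small increase cannot be excluded. Loss of S-phase copies could give a spread of 0.629 and cannot be told apart from the treatment, since no input library was used here. GC bias and the treatment itself also remain open, with 1 library and no replicate. Over 1 Mb windows high NaCl resembled UV (rho 0.97, spread between them 0.29), which has the second pattern and many short fragments. With 1 library each, this likeness does not decide between the explanations for either shift.

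The third pattern is the smaller shift in UV. A sequencing run as marked by aligner scores is argued against because 1.48% of UV reads had score 9, close to control (1.51%) and unlike high NaCl and return replicate 1, while run differences that scores do not mark remain open. Short fragments were 45.3 percentage points more common in UV than in control, and as the only UV library is also the one cut short, digestion and UV light cannot be told apart. The UV treatment itself stays among the open explanations.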

How the results depend on the processing

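Alternatives on aligner score, top windows, the X chromosome and those across chromosomes were chosen after the data had been seen, and the others before. Of the alternative counts of 100 kb windows, 63 stayed within 1.5 times in total and 7 moved, but 20 of the 63 are counts of 0 for high NaCl and bleomycin, which say little about stability. Counts by direction moved further under scaling: with TMM factors, lower windows went from 1983 to 63 for return against UV and from 4174 to 1545 for return against high NaCl. Over 1 Mb windows, of which there are fewer, counts were 1768 for return against control, 1306 against high NaCl, 1705 against bleomycin, 1407 against UV, and 0 for UV against control. The UV count was 48 with TMM factors and 2 at the top aligner score, and the cause was not tested. With at most 1 read per position and strand, the top 1% of 10 kb windows held 3.29% of reads in control, 3.29% in bleomycin, 2.92% in UV, 3.09% in high NaCl, and 3.42% and 3.61% in return, and without the top 0.1% of windows 2.68%, 2.75%, 2.44%, 2.46%, 2.87% and 3.23%, both by construction. The 7 rank correlations between libraries moved little over 1 Mb windows. Across chromosomes, 10 alternatives kept their side of 0.05. For return, rho on the autosomes was -0.42 (permutation p = 0.076), leaving out each replicate gave -0.64 to -0.42, and the other alternatives gave -0.53 with at most 1 read per position and -0.51 without the top windows. For bleomycin, rho was 0.61 with at most 1 read per position and 0.46 without the top windows, both past 0.05 before adjustment, and the cause was not tested.

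Counts of windows without either return replicate were not run as tests, since no residual degree of freedom is left. Alternatives for gene deserts, genes, annotation classes and gene density in windows were not run, because genes could not be placed on the build of the files. No paired analysis was possible because the labels number only the return libraries, and nothing ties a library of 1 group to a library of another. In data simulated for high NaCl against control at 100 kb, with few windows changed, 10% of rises and 4% of falls of 0.5 on the log2 scale were called. The part played by depth was not tested.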

Other observations

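All tests and values in this part were chosen after the data had been seen. A block on chromosome 5 from 31800001 to 32700000 carried far more reads than its surroundings in every library. The mean per 100 kb over its 9 windows was 14.3 times the median of the flanks in control, 11.7 in bleomycin, 10.96 in UV, 13.7 in high NaCl, and 13.9 and 9.21 in return replicates 1 and 2. The 1 Mb windows of chromosome 5 from 31000001 and from 32000001, named above among the lowest in return, hold this block.

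In return replicate 2, 18 windows of 10 kb had at least 200 reads and at least 5 times the median of the other libraries, with 59904 reads or 0.670% of that library. On chromosome 17 from 39450001 to 39460000 there were 47741 reads, 16.3 times the median, at 4189 distinct positions. This window lies within the 1 Mb window of chromosome 17 that had the highest mean in return. Chromosome 11 from 108820001 to 108830000 had 2425 reads (13.6 times), and chromosome 6 from 3150001 to 3160000 had 1136 (17.8 times).

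In bleomycin, counted as distinct positions, the 10 kb windows with the highest ratios to control were on chromosome 12 from 106840001 to 106850000 (log2 1.53, 101 positions against 32), chromosome 5 from 120060001 to 120070000 (1.48, 122 against 40) and chromosome 13 from 79970001 to 79980000 (1.45, 60 against 20). The same windows had mean log2 ratios to control of 1.55, 1.19 and 2.21 in return. These were the extremes of many windows and were not tested, and the shared control library raises both ratios where control was low by chance.

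A hypothesis that signal near the distal 5 Mb of chromosomes may fall in return was not borne out or excluded. The mean difference from the rest of each chromosome was -0.055 (log2, SD 0.53 over 20 chromosomes, lower in 13, two-sided sign-flip permutation p = 0.64, adjusted 0.74 over 6 tests). In UV the difference was -0.15 (SD 0.21, lower in 15 of 20, permutation p = 0.0065, adjusted 0.039). Chromosomes are not replicates, so these p-values describe single libraries set against the same control library, and short fragments also differed between UV (65.2%) and control (19.98%).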
